A study of Homo sapiens with 9 samples.

How the data were processed

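RNA from SaOS2 cells in 3 groups of 3 samples (untreated control, doxycycline for 3 days, and recovery for 3 days after doxycycline) was labelled with a single dye, per the labels' protocols, and the probe identifiers and column headers are those of Illumina bead arrays. The table of signals holds an averaged intensity for each of 47322 probes on each array, as deposited by the authors, not normalized between arrays and with values below 0 on 29.2% to 32.5% of probes, so a background had been subtracted; the software is not given in the sources used here. Beside each intensity stands a detection p-value, deposited by the authors per the file headers, in steps of 1 in 770. A second deposited table by the authors holds intensity values on the linear scale that are quantile normalized, with a median from 14.39 to 14.44 in every column.

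Columns of the signal table carry short codes in place of sample names. They were assigned to samples by rank identity with the sample-named columns of the normalized table, with a rank correlation of 1.0 for the assigned column and at most 0.962 for any other. The alternative that uses the authors' processed values does not rest on this assignment.

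Gene names came from the annotation of the probes, with 30112 probes that had 1 symbol, 8 that had several and 17202 that had none; 30073 matched a RefSeq gene identifier, and 0 symbols were updated. The signals were background corrected with the normexp model of limma, using the detection p-values to estimate the background, with an offset of 16, then log2 transformed and quantile normalized. Probes with a detection p under 0.05 on at least 3 arrays were kept, 22039 in number, and each gene was represented by its brightest kept probe, which left 12245 genes. The 5666 kept probes without 1 gene name were tested apart.

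Group means were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 9 arrays, which left 6 residual degrees of freedom and a prior of 5.51. The 3 contrasts and the F-test over the 3 groups used Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05. Gene lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, with the estimated correlation as an alternative. Of 30 lists fixed before the data were examined, 29 were tested, and 1, of mitochondrially encoded genes, had 0 measured members. Tables were prepared and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

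Genes named in the report were chosen by a rule set before the data were examined: APC, the 10 largest rises and 10 largest falls per contrast among called genes whose arrays do not overlap, up to 4 members with the smallest p from each list described, and the 5 largest differences among genes still changed and among genes that moved back. Provisional gene names were left out. Where a gene was not detected in the dimmer group, the fold is given as a lower bound against the lowest detected signal of the array. This rule and the lists added later gave 53, 40 and 42 genes with 2 or more kept probes, in the 3 contrasts in the order of the report. The kept probes differed in sign for 7, 6 and 3 of them, of which 0, 5 and 1 were called. Not all of these genes are named in the report.

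The alternatives tried were another offset, no background correction, median scaling, cyclic loess, other filters, the authors' processed values, a mean over probes, a trended robust prior, array weights, a replicate block, fits of the compared groups alone, a minimum log2 difference of 1 and leaving out each array. Once sorted, the authors' processed values lay within 0.6 intensity units of the mean quantiles of the deposited signals. That alternative and the one without background correction therefore nearly repeat each other. No slide or chip is named in the sources used here. The number of arrays limits the precision: in 20 simulations of the doxycycline and control comparison over 12245 genes with 200 changed, 22.7% of changes of 0.5 on the log2 scale were recovered, 95.7% of changes of 1 and 100% of changes of 2, and 5.6% of calls were unchanged genes. Simulated genes varied independently, with the same spread in every group. In the data the median spread was 0.217 for doxycycline, 0.117 for control and 0.119 for recovery, so these rates may not hold there. Every column of sample values was assigned, and none was left out.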

Results

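Gene expression was measured on 9 single-colour bead arrays in SaOS2, a human osteosarcoma cell line with osteoblast-like traits. The cells carried a doxycycline-inducible construct for an antisense RNA to APC, the scaffold protein of the complex that marks beta-catenin for degradation. There were 3 untreated control arrays, 3 arrays of cells kept in doxycycline at 1 µg/ml for 3 days, and 3 recovery arrays of cells treated the same way and then grown for 3 further days without the drug. Between 20141 and 21317 of 47322 probes were detected per array. The analysis covered 12245 genes. Differences are given as log2 difference ± standard error from limma with Benjamini-Hochberg adjusted p, over 3 arrays per group. Nothing in the sources used here says whether the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical.

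Arrays separated by group along the first principal component, with controls from -22.74 to -22.22, doxycycline arrays from -10.59 to -7.24 and recovery arrays from 28.21 to 35.62. Doxycycline replicate 2 stood apart on the second component, at -47.75 against 5.99 and -10.45 for the other doxycycline arrays. The median over genes of the standard deviation within a group was 0.217 on the log2 scale for doxycycline, 0.117 for control and 0.119 for recovery.

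**Figure D1:**
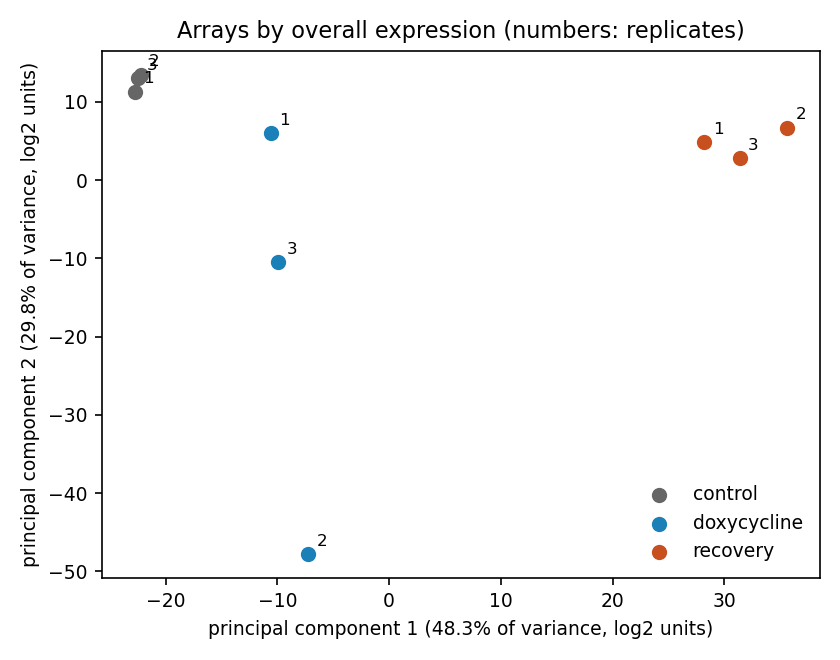
Scores of the 9 arrays on the first and second principal components of the normalized log2 levels (48.3% and 29.8% of variance), coloured by group and numbered by replicate. The groups separate along the horizontal axis, and doxycycline replicate 2 lies at -47.75 on the vertical axis.

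The target of the antisense RNA was read by 1 probe (ILMN_1662668), whose sequence and strand were not analysed here, and which lay near background. APC was detected on 1 of 3 control arrays and on 3 of 3 arrays in each other group. Its mean level was 5.29 ± 0.34 (SD, n = 3) in control, 5.42 ± 0.02 in doxycycline and 5.41 ± 0.12 in recovery. No difference passed the threshold, with 0.13 ± 0.16 for doxycycline against control (adjusted p = 0.62, 95% interval -0.21 to 0.48), 0.12 ± 0.16 for recovery against control (adjusted p = 0.64) and -0.01 ± 0.16 for recovery against doxycycline (adjusted p = 0.97). A signal this close to background cannot show a moderate loss of the transcript.

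The comparison of doxycycline with control asked what 3 days of induction changed. Genes of the interferon response rose together, led by RSAD2, the antiviral radical enzyme viperin (2.79 ± 0.17, a 6.93-fold rise), OAS2 and OASL of the oligoadenylate synthetase family (2.65 ± 0.12 and 2.22 ± 0.15), MX2, a dynamin-like antiviral GTPase (2.55 ± 0.14), and IFIT3 (2.01 ± 0.13). TNFSF10, the death ligand TRAIL, was not detected on any control array and was at least 3.57-fold higher. CEACAM1, a cell adhesion molecule, rose by 2.17 ± 0.20, the amino acid oxidase IL4I1 by 1.96 ± 0.19, the guanylate-binding protein GBP4 by 1.95 ± 0.14 and the helicase HELZ2 by 1.92 ± 0.20. The largest falls were smaller: SNORD13, a small nucleolar RNA (-1.22 ± 0.24), the translation regulator BZW1 (2.01-fold lower), and the ribosomal protein genes RPL26 (-1.02 ± 0.20), RPL24 (1.99-fold lower) and RPL7 (-0.88 ± 0.14). Also among the largest falls were the pseudogene UQCRBP1 (-0.89 ± 0.19), the G-protein regulator RGS10 (-0.88 ± 0.19), the glutathione-degrading enzyme CHAC2 (-0.88 ± 0.18), the polarity scaffold LIN7C (-0.86 ± 0.18) and the methyltransferase gene LRTOMT (-0.85 ± 0.19). The calls of SNORD13 (-1.07, limma adjusted p = 0.06), RGS10 (-0.69, limma adjusted p = 0.054) and LRTOMT (-0.64, limma adjusted p = 0.056) ended without doxycycline replicate 2, and none of the falls named here was called in every leave-one-out fit. Over 22 alternatives the call of RPL7 was lost in 1, those of BZW1, RPL24 and RPL26 in 8, and the other 6 in 10 (SNORD13) to 13 (RGS10 and LRTOMT). Values are those of the brightest probe. The smallest difference among the kept probes was 0.21 for OAS2, 1.23 for OASL, 0.48 for CEACAM1, 0.49 for IFIT3, -0.54 for BZW1, -0.48 for RGS10 and -0.53 for LRTOMT. Ribosomal protein genes were also lower on doxycycline replicate 2 than on the other doxycycline arrays, by a median of -0.27.

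Of the 12245 genes, 254 changed, 210 up and 44 down, and 82 of these by at least 1 on the log2 scale. Leaving out 1 array at a time moved this count from 76 (without control replicate 2) to 2614 (without doxycycline replicate 1), and 67 genes, all higher and 23 of them in the interferon list, were called in every such fit. With the authors' processed values 129 genes changed, 122 up and 7 down, without background correction 128, 121 up and 7 down, and with array weights 3210, 1900 up and 1310 down. Without doxycycline replicate 2 the count was 239, of which 204 were among the 254. When only control and doxycycline arrays were fitted it was 84, 83 up and 1 down, so nearly all falls depend on including the recovery arrays.

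**Figure D2:**
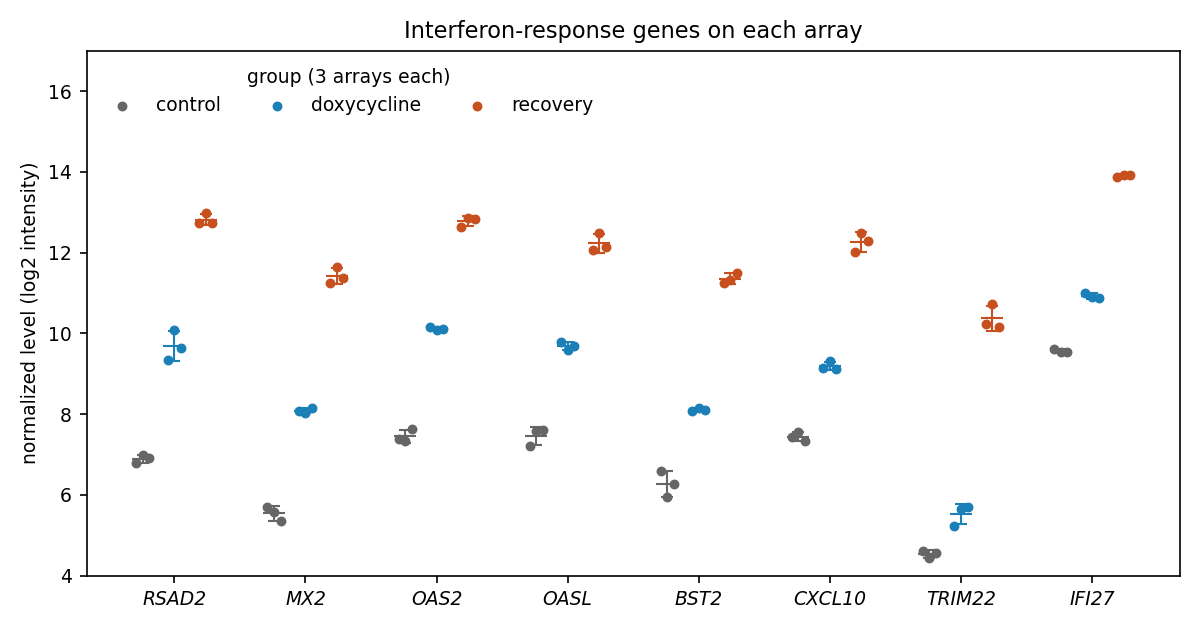
Normalized level (log2 intensity) of 8 interferon-response genes on each array, as points, with the group mean and SD over 3 arrays. Every doxycycline array lies above every control array and below every recovery array for these genes; TRIM22 was not detected on the control arrays.

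Of 29 gene lists tested with camera, 12 were called, 6 up and 6 down, and only the interferon list kept its call with an estimated correlation. Mixed splits of these arrays, given further below, called up to 11 lists at the preset correlation. In the interferon list 31 of 35 measured genes rose and none fell over all genes tested, and 34 rose adjusted over the list alone (median 1.37, camera adjusted p = 1.4e-46, and adjusted p = 0.0098 with an estimated correlation). Without doxycycline replicate 2 the count was 32. In the NF-kB and inflammation list 6 of 21 rose and none fell, and 12 rose adjusted over the list alone (camera adjusted p = 5.8e-07, adjusted p = 0.18 with an estimated correlation). Its risen members included the cytokines IL6 (1.23 ± 0.18) and IL11 (0.76 ± 0.14), PTGS2, the inducible cyclooxygenase (0.83 ± 0.17), and the chemokine CCL5 (0.80 ± 0.16), whose call ended without doxycycline replicate 2 (0.74 ± 0.17, limma adjusted p = 0.056). Of 22 alternatives 12 lost the call of PTGS2, 9 that of CCL5, 4 that of IL11 and 0 that of IL6.

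Smaller shifts upward came from lists in which few genes passed singly. None of 20 endoplasmic reticulum chaperone genes passed over all genes, and 12 were up and 1 down adjusted over the list alone (median 0.44, camera adjusted p = 9.1e-05, adjusted p = 0.66 with an estimated correlation), with CALR at 0.65 ± 0.18 and HYOU1 at 0.75 ± 0.22. Leaving out doxycycline replicate 2, on which lysosome and endoplasmic reticulum genes lay a median of 0.58 above the other doxycycline arrays, left 1 up and 1 down adjusted over the list alone, and a median of 0.24. Among YAP/TAZ targets 1 of 22 rose, NT5E, the ectonucleotidase CD73 (1.01 ± 0.18), and 3 adjusted over the list alone (camera adjusted p = 0.0013, adjusted p = 0.32 with an estimated correlation). Among mesenchymal and epithelial adhesion genes 1 of 21 rose, the collagenase MMP13 (at least 1.59-fold), and 6 adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.66 with an estimated correlation). Of 18 immediate early genes KLF4 alone rose (0.67 ± 0.15), and 2 adjusted over the list alone (camera adjusted p = 0.039, adjusted p = 0.66 with an estimated correlation). The list and KLF4 were not called without doxycycline replicate 2 (limma camera adjusted p = 0.099 for the list, limma adjusted p = 0.065 for KLF4 at 0.58 ± 0.14), and 4 immediate early genes then rose adjusted over the list alone. The list lost its call in 6 of 23 alternatives, KLF4 in 11 of 22, and the adhesion list in 3 of 23. Leaving out doxycycline replicate 2 lowered the median from 0.28 to 0.16 for YAP/TAZ targets and from 0.32 to 0.14 for adhesion genes.

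Downward, no single gene passed over all genes in any of the 6 lists called. The medians were -0.18 for 34 mitochondrial ribosome and translation genes (camera adjusted p = 0.00033), -0.17 for 41 nuclear-encoded respiratory chain genes (0.00097), -0.12 for 27 S phase genes (0.0072), -0.12 for 32 G2/M genes (0.033), -0.14 for 13 NRF2 oxidative stress genes (0.033) and -0.16 for 18 heat shock genes (0.043). With an estimated correlation the adjusted p was 0.66 for the mitochondrial ribosome, respiratory chain, S phase and heat shock lists and 0.67 for the G2/M and NRF2 lists. Adjusted over the list alone, 1 S phase gene was down, and none in the other 5 lists. Examples, none past the threshold, were MRPS15 (-0.42 ± 0.13), COX7B (-0.55 ± 0.16), RRM2 (-0.52 ± 0.13) and CDK1 (-0.36 ± 0.13). Without doxycycline replicate 2 the G2/M, NRF2 and heat shock lists were not called (limma camera adjusted p = 0.37, 0.24 and 0.3). Over 23 alternatives they lost their calls in 5, 6 and 9. The metallothionein list, at camera adjusted p = 0.08 with all arrays, was called upward without that array (limma camera adjusted p = 0.0053, adjusted p = 0.36 with an estimated correlation), with 4 of 5 genes up adjusted over the list alone. The medians without that array were -0.07 for the mitochondrial ribosome, -0.09 for the respiratory chain, -0.06 for S phase, -0.02 for G2/M, -0.04 for NRF2 and -0.05 for heat shock, and no S phase gene was then down adjusted over the list alone.

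Wnt/beta-catenin targets were not called as a list (camera adjusted p = 0.053, adjusted p = 0.66 with an estimated correlation). They were called upward in 2 of 23 alternatives, with a stricter detection filter (limma camera adjusted p = 0.032) and without control replicate 1 (0.021). Without doxycycline replicate 2 the list was not called (limma camera adjusted p = 0.15). Its median was then 0.12, against 0.16 with all arrays, and 3 members rose over all genes. Of 23 measured, 2 rose over all genes and 3 adjusted over the list alone: CCND1, cyclin D1, by 1.32 ± 0.21, CD44, the hyaluronan receptor, by 0.97 ± 0.17, and, only in the adjustment over the list alone, NOTUM (0.57 ± 0.17). None of 16 genes of the beta-catenin destruction complex and none of 20 osteoblast differentiation genes passed, by either adjustment. Single members passed elsewhere, among them COL9A2, a cartilage collagen (0.65 ± 0.14), the BH3-only gene PMAIP1 (0.72 ± 0.14), the amino acid transporter SLC7A5 (1.06 ± 0.20) and the ribosome biogenesis gene RRP12 (0.55 ± 0.12). Of 10 haematopoietic markers measured, CD68, a lysosomal protein abundant in macrophages, rose by 0.91 ± 0.13, and of 5 epithelial markers the tight junction gene CLDN4 was at least 1.3-fold lower. Without doxycycline replicate 2 the calls of COL9A2 (0.54 ± 0.13, limma adjusted p = 0.07), RRP12 (0.54 ± 0.12, limma adjusted p = 0.053) and CLDN4 (limma adjusted p = 0.074) ended. Of the genes named in this paragraph, CCND1 and CD68 were called in every leave-one-out fit, and CD44, COL9A2, PMAIP1, SLC7A5, RRP12 and CLDN4 were not. COL9A2 lost its call in 16 of 22 alternatives, CLDN4 in 14 of 20 and RRP12 in 12 of 22. The smallest difference among kept probes was 0.61 for CD44 and 0.59 for CD68.

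**Figure D3:**
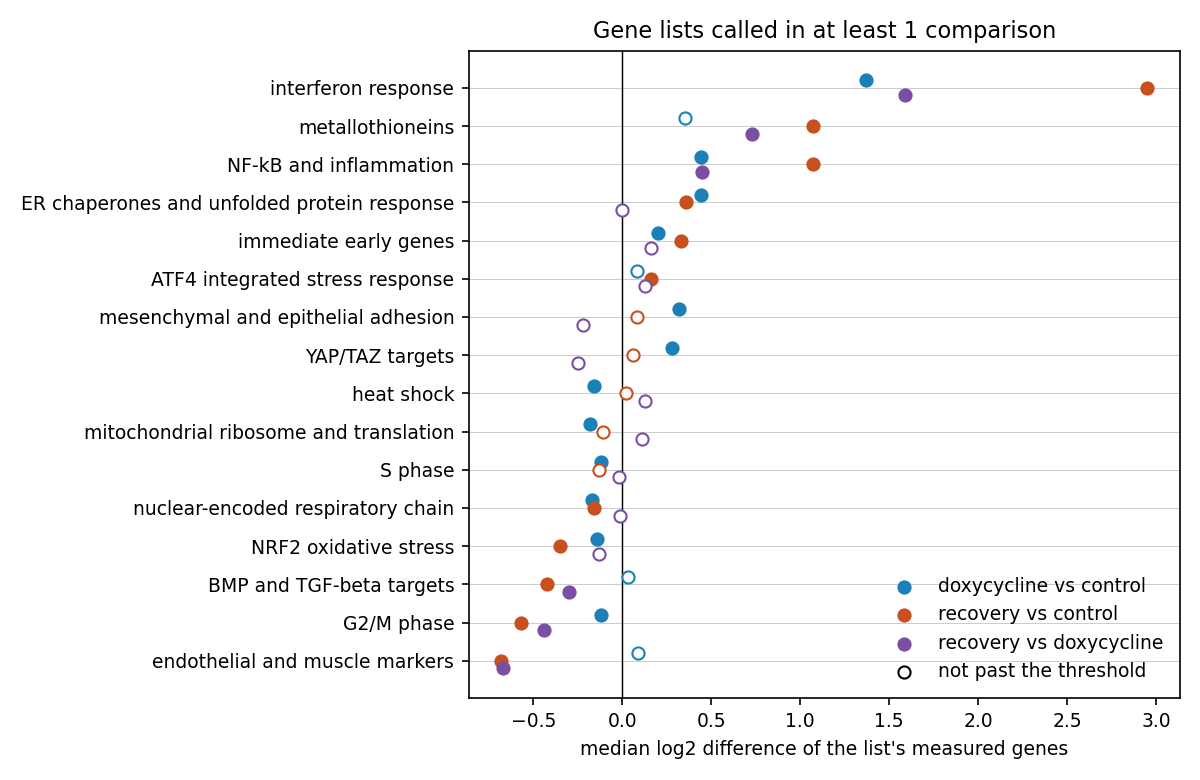
Median log2 difference of the measured genes of each list called in at least 1 comparison, with 1 point per comparison; filled points passed the camera threshold and open points did not. The interferon list has medians of 1.37, 2.95 and 1.59.

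Recovered cells were compared with control cells to see what remained or arose 3 days after withdrawal. The interferon genes were far above control: RSAD2 by 5.92 ± 0.17, MX2 by 5.87 ± 0.14, OAS2 by 5.32 ± 0.12, BST2, the virion-tethering protein tetherin, by 5.09 ± 0.16, and the chemokine CXCL10 by 4.82 ± 0.14. OASL rose by 4.77 ± 0.15, the exonuclease ISG20 by 4.65 ± 0.13 and IFI27 by 4.33 ± 0.10. TRIM22, an antiviral ubiquitin ligase, and TNFSF10 were not detected on control arrays and were at least 33.7-fold and 35.6-fold higher. The largest falls were in SOST, which encodes the Wnt inhibitor sclerostin (-2.24 ± 0.15), the long noncoding RNA DANCR (-2.24 ± 0.23), the aggrecanase ADAMTS5 (-2.18 ± 0.19), the histone gene H2AC25 (-2.03 ± 0.17) and the cytosolic aconitase ACO1 (-2.03 ± 0.16). Smaller were TMEM170B (-1.84 ± 0.12), PROM1, the stem cell marker prominin (-1.84 ± 0.18), PRR11 (-1.79 ± 0.13), the myosin light chain MYL1 (-1.78 ± 0.21) and the ceramide kinase CERK (-1.75 ± 0.14), whose other kept probe gave 0.28. The lowest kept probe of OAS2 gave 2.74.

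In all, 2353 genes changed, 1243 up and 1110 down, 473 of them by at least 1 on the log2 scale. The count lay between 1351 (without recovery replicate 2) and 3819 (without doxycycline replicate 2) when 1 array was left out, and was 4037 when only control and recovery arrays were fitted. Called in every leave-one-out fit were 1163 genes, 670 up and 493 down.

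Camera called 11 lists, 6 up and 5 down, of which the interferon list alone kept its call with an estimated correlation on all 9 arrays. All 35 measured interferon genes rose, over all genes and adjusted over the list alone (median 2.95, camera adjusted p = 9.1e-54, adjusted p = 0.0065 with an estimated correlation). Of 21 NF-kB and inflammation genes 18 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 5.3e-12, adjusted p = 0.051 with an estimated correlation). IL6 rose by 2.73 ± 0.18, CCL5 by 2.49 ± 0.16, the NF-kB inhibitor TNFAIP3 by 1.57 ± 0.15 and SOD2, the mitochondrial superoxide dismutase, by 1.74 ± 0.18. Of 5 metallothioneins, which bind zinc and copper, 4 rose by either adjustment (camera adjusted p = 0.00011, adjusted p = 0.19 with an estimated correlation), with MT1G at 2.36 ± 0.24 and MT2A at 1.93 ± 0.16.

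Of 20 endoplasmic reticulum chaperone and unfolded protein response genes 5 rose by either adjustment (camera adjusted p = 0.0023, adjusted p = 0.68 with an estimated correlation), among them DNAJB9 (1.01 ± 0.14), XBP1 (0.93 ± 0.14) and HSPA5 (0.89 ± 0.21). When doxycycline replicate 2 was left out, 12 of 19 measured rose over all genes, and 15 rose and 1 fell adjusted over the list alone. In the ATF4 list 7 of 31 rose and 1 fell, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.042, adjusted p = 0.19 with an estimated correlation). It was not called without that array, where 2 genes fell by either adjustment. DDIT3, the stress factor CHOP, rose by 1.29 ± 0.12, CEBPB by 0.97 ± 0.11 and the tryptophanyl-tRNA synthetase WARS1 by 1.25 ± 0.15, and VLDLR fell by 1.48 on the log2 scale. Immediate early genes went both ways, 6 up and 2 down of 18, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.38 with an estimated correlation). KLF4 (1.57 ± 0.15) and NR4A2 (1.19 ± 0.14) rose, while FOS (-1.42 ± 0.17) and KLF2 (-1.08 ± 0.13) fell.

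G2/M genes were lower, 26 of 32 over all genes and 27 adjusted over the list alone, with none higher (median -0.57, camera adjusted p = 5.3e-12, adjusted p = 0.19 with an estimated correlation). Without doxycycline replicate 2 this list too kept its call, at adjusted p = 0.043 with an estimated correlation. They included TOP2A, the DNA topoisomerase of dividing cells (-0.68 ± 0.10), the cyclins CCNB1 (-0.70 ± 0.13) and CCNB2 (-0.76 ± 0.13), and CENPF (-0.74 ± 0.14). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 1.21 ± 0.15 in a p53 target list that was not called (5 of 20 up, 3 down, by either adjustment). Of 20 BMP and TGF-beta targets 8 fell and 1 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0023, adjusted p = 0.11 with an estimated correlation). The actin-cytoskeleton genes ACTA2 (-1.40 ± 0.11) and TAGLN (-1.57 ± 0.14) and the TGF-beta signalling inhibitor PMEPA1 (-1.27 ± 0.17, or -0.55 at its other kept probe) were among the falls. Of 6 endothelial and muscle markers 3 fell, or 4 adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.19 with an estimated correlation), among them cardiac actin ACTC1 (-1.19 ± 0.16) and the creatine kinase CKM (-1.02 ± 0.13). Of 13 NRF2 genes 2 fell, NQO1 (-0.82 ± 0.14) and PGD (-0.40 ± 0.11), or 4 adjusted over the list alone (camera adjusted p = 0.004, adjusted p = 0.62 with an estimated correlation). Of 41 respiratory chain genes 3 fell, or 1 adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.62 with an estimated correlation), cytochrome c, CYCS (2-fold lower), ATP5PO (-0.47 ± 0.13) and NDUFA1 (-0.41 ± 0.12). By either adjustment, 8 NRF2 genes fell, and 9 respiratory chain genes fell and 1 rose, when doxycycline replicate 2 was left out.

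Wnt/beta-catenin targets went both ways, 4 up and 4 down of 23, or 7 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.82). CCND1, which had no probe detected on all 9 arrays, rose by 3.55 ± 0.21, and the transcription factor SP5 was at least 1.51-fold higher. DKK1, a secreted Wnt inhibitor (-1.44 ± 0.16), and BMP4 (-0.88 ± 0.14) fell. In the destruction complex AMER1 (0.56 ± 0.16, or 0.85 at its other kept probe) and BTRC (0.37 ± 0.11) rose over all genes, and none of 16 passed adjusted over the list alone. Their calls were lost in 6 and 9 of 22 alternatives. Among 20 osteoblast genes 3 rose, BMP2 (1.16 ± 0.12), SPARC (0.90 ± 0.16) and the vitamin D receptor VDR (0.66 ± 0.16), and SOST fell, with 4 up and 3 down adjusted over the list alone and no call for the list. These counts also moved without doxycycline replicate 2: over all genes 8 Wnt targets rose and 5 fell, and 4 osteoblast genes rose and 4 fell, while in the destruction complex 2 rose and 3 fell by either adjustment. MMP13 was at least 8.56-fold higher and NT5E rose by 2.08 ± 0.18. Without doxycycline replicate 2 the ATF4, immediate early and endothelial and muscle lists were not called (limma camera adjusted p = 0.053, 0.07 and 0.068). Over all alternatives the ATF4 call was lost in 9 of 23 and the endothelial and muscle call in 7 of 21. Of 10 haematopoietic markers CD68 (2.49 ± 0.13, or 1.02 at its other kept probe) and CSF1R (0.65 ± 0.20, its call lost in 12 of 22 alternatives) rose, and LCP1 (-0.68 ± 0.14) and CORO1A (-0.62 ± 0.12) fell.

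Recovery was set against doxycycline to follow expression after the drug was removed. The interferon genes were higher again, TRIM22, detected on 2 of 3 doxycycline arrays, by 4.85 ± 0.17, MX2 by 3.32 ± 0.14, TNFSF10 by 3.32 ± 0.16, BST2 by 3.25 ± 0.16, RSAD2 by 3.13 ± 0.17 and CXCL10 by 3.07 ± 0.14. CASP1, the inflammatory caspase, rose by 3.62 ± 0.20, complement factor B, CFB, by 3.16 ± 0.24 and the small nucleolar RNA SNORD3D by 3.02 ± 0.24, and the nucleotide kinase CMPK2, not detected on doxycycline arrays, was at least 7.24-fold higher. The largest falls were in CRISPLD2 (-2.28 ± 0.21), ADAMTS5 (-2.02 ± 0.19), SOST (-1.96 ± 0.15), TAGLN (-1.83 ± 0.14) and DANCR (-1.80 ± 0.23). They went on with the growth factor receptor FGFR3 (-1.74 ± 0.21, or -0.38 at its other kept probe), REEP1 (-1.70 ± 0.13), the heparan sulfate proteoglycan GPC1 (-1.67 ± 0.21), the collagen gene COL18A1 (-1.65 ± 0.25) and H2AC25 (-1.65 ± 0.17).

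Between these arms 2254 genes differed, 1067 up and 1187 down, 366 of them by at least 1 on the log2 scale. Without 1 array the count ran from 1048 (without recovery replicate 2) to 3279 (without doxycycline replicate 1), and it was 1428 when only these 6 arrays were fitted. In the test over all 3 groups 2747 genes differed.

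Of the 6 lists called, 3 up and 3 down, the interferon list alone kept its call with an estimated correlation on all 9 arrays, with 30 of 35 genes up and none down, or 32 up adjusted over the list alone (median 1.59, camera adjusted p = 5.2e-34, adjusted p = 0.023 with an estimated correlation). Of 21 NF-kB and inflammation genes 10 rose and 1 fell, or 15 and 1 adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.11 with an estimated correlation), with CCL5 up by 1.70 ± 0.16 and the chemokine CCL2 down, at -1.06 ± 0.12. Metallothioneins rose in 4 of 5 cases by either adjustment (camera adjusted p = 0.00062, adjusted p = 0.3 with an estimated correlation). G2/M genes fell in 15 of 32 cases, or 18 adjusted over the list alone (camera adjusted p = 5.8e-08, adjusted p = 0.3 with an estimated correlation), with the proliferation marker MKI67 at -1.32 ± 0.19. When doxycycline replicate 2 was left out the numbers were 27 and 28, and the list kept its call (adjusted p = 0.046 with an estimated correlation). BMP and TGF-beta targets fell in 9 of 20 cases and rose in 1, by either adjustment (camera adjusted p = 0.00075, adjusted p = 0.11 with an estimated correlation). Endothelial and muscle markers fell in 5 of 6 (camera adjusted p = 0.002, adjusted p = 0.11 with an estimated correlation), or 3 of 5 over all genes without that array. CCND1 rose by a further 2.23 ± 0.21 and DKK1 fell, at -1.14 ± 0.16 (-0.51 at its other kept probe), among 23 Wnt targets of which 2 rose and 5 fell, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.39), and 4 and 6 without doxycycline replicate 2. The NRF2 list, not called with all arrays, was then called downward (limma camera adjusted p = 0.025, adjusted p = 0.26 with an estimated correlation). With all arrays, 1 of 16 destruction complex genes rose over all genes, CSNK1A1, and 1 fell, AXIN2, which is also in the Wnt list. None passed adjusted over the list alone, and the list was not called (camera adjusted p = 0.82). These calls were lost in 12 (CSNK1A1) and 4 (AXIN2) of 22 alternatives.

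**Figure D4:**
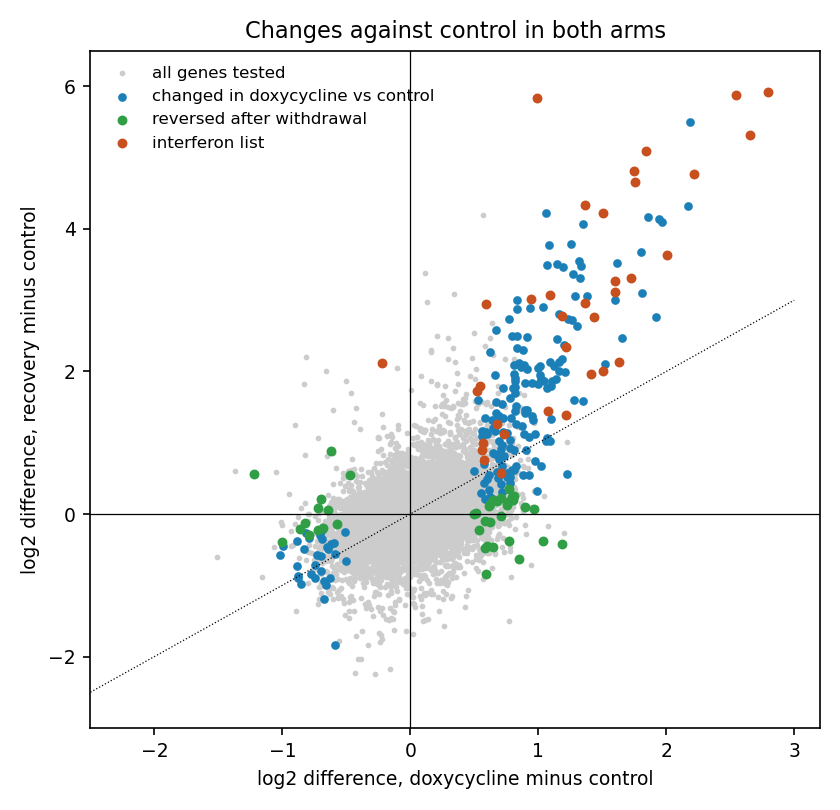
Log2 difference from control in the doxycycline arm (horizontal axis) and in the recovery arm (vertical axis) for each gene tested; the dotted line marks equal values. Of the 254 genes changed in doxycycline, 191 were still changed in recovery in the same direction, and 40, in green, moved back.

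The fate of the doxycycline-changed genes after withdrawal was followed gene by gene. Of the 254, 191 were still changed in recovery in the same direction, 171 higher and 20 lower, and 122 of these had moved further from control. The 191 became 73 (without control replicate 2) to 840 (without doxycycline replicate 1) when 1 array was left out, and 118 with the authors' processed values. All 31 changed interferon genes were still higher, 27 had risen further, and none moved back. Lists drawn independently would share 25.3 genes, and part of the excess can come from the shared control arrays. Simulations of unchanged groups gave 0, as no gene changes in them, and do not measure that part. Moving back toward or past control were 40 genes, 27 that had risen and 13 that had fallen, against 24.2 from independent lists, and the shared doxycycline arrays can add to this count by an amount that was not measured. They included the collagen gene COL6A2 (1.18 ± 0.23 in doxycycline against control, with 0.02 at the lowest of its 3 kept probes), the spectrin SPTB (1.04 ± 0.18), FSTL3, a follistatin-like activin inhibitor (0.97 ± 0.16), SNORD13 and BZW1. For 34 of the 40, doxycycline replicate 2 lay further from control than replicate 1, a share not computed for the other changed genes. Without doxycycline replicate 2, 27 genes moved back, and with the authors' processed values 9. Without 1 array the count ran from 3 (without control replicate 2) to 1028 (without doxycycline replicate 1). A further 23 of the 254 met neither rule.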

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

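The tests of blood cells, of normalization, of exchanged group labels, of a wrong array under the doxycycline label, and the splits for the interferon list were chosen only after the result was seen.

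Probes without 1 gene name stood outside the comparisons of the report. Of 5666 such probes 63 passed the threshold in doxycycline against control (23 up, 40 down), 642 in recovery against control (235 up, 407 down) and 418 in recovery against doxycycline (209 up, 209 down). The largest difference was at probe ILMN_3259146, at 5.3 ± 0.14 on the log2 scale in recovery against control, 1.99 in doxycycline against control and 3.31 in recovery against doxycycline. No explanation was tested for these probes.

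The interferon genes were higher 3 days after doxycycline was removed than during it, by a median of 1.59. Blood cells in the recovery cultures would be expected to raise their own markers, by an amount not known here. The 10 of 22 haematopoietic markers measured had a median difference of -0.22 (SD 0.7), below 1.59 by more than that spread. They went both ways, and CD68 rose by 1.57 (0.42 at its other kept probe). The markers as a set did not rise, but this comparison was not calibrated. Normalization or background correction as the whole cause is argued against by 29 of 35 interferon genes still higher in the least favourable of 5 other corrections or value tables. Among these 5, the authors' processed values nearly repeat the signals without background correction. An exchange of the doxycycline and recovery labels as whole groups cannot be told apart, since the median of the ATF4 list, 0.13, decides nothing and APC, the target, differed in no comparison. Time in culture and the lack, among the arrays analysed here, of doxycycline-treated cells without the antisense construct also remain open, so that a continuing response to the antisense RNA is only 1 untested explanation.

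Doxycycline replicate 2 lay apart from the other arrays. Lysosome and endoplasmic reticulum genes were higher on it, relative to genes of cytosolic complexes, by 0.95 against its group mates, where the other arrays lay between -0.73 and 0.12, which may reflect loss of cytosolic RNA from that sample. The lower end of the range, here and in the next comparison, was doxycycline replicate 1. Its group mates include replicate 2, so it is not an independent reference. The same comparison of short secretory transcripts against ribosomal protein genes gave 0.23 (other arrays -0.47 to 0.13), and transcript length cannot be told apart from the first explanation by it. A recovery array under the doxycycline label is argued against by 29 of 31 called interferon genes that lie on this array between the highest control and the lowest recovery array. These genes cannot test for a control array under that label. They were called with this array included, and on all 254 called genes the doxycycline and control arrays do not overlap. A biological difference of that culture was not tested.

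Other splits of the arrays were also run. For each pair of groups there are 10 splits, too few for a share under 0.05. In doxycycline against control 1 split, the real one, gave as many as 254 genes (highest other 0), 1 gave 12 lists (highest other 11) and 1 gave 31 interferon genes (highest other 0). In recovery against control the numbers were 1 for 2353 genes (highest other 0), 1 for 11 lists (highest other 8) and 1 for 35 interferon genes (highest other 0). In recovery against doxycycline they were 1 for 2254 genes (highest other 0), 5 for 6 lists (highest other 12) and 1 for 30 interferon genes (highest other 0). Since mixed groups called up to 11, 8 and 12 lists, a list call at the preset correlation alone does not mark a difference between the groups. Of 100 splits of all 9 arrays, 1 gave as many as 2747 genes differing among 3 groups (highest other 1856), a share under 0.05. Only 9 of the other splits gave any gene, and technical replicates could not be exchanged between groups. The share therefore describes these arrays and does not exclude chance. Of the same splits 2 gave as many as 40 genes moving back (highest other 1101) and 2 as many as 191 genes still changed (highest other 965), but mixed groups call almost no genes, so these counts were near 0 beforehand and say nothing about the overlap that shared arrays bring. The splits with 1101 and 965 keep the 3 recovery arrays together under another group's name, which points to a structure of the samples: the recovery arrays lie apart from all others.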

How the results depend on the processing

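The array weights by the gene-by-gene method (the default did not converge), the alternatives for the interferon list and the lists without doxycycline replicate 2 were chosen after seeing the data. The interferon list was called upward in all 3 comparisons under every alternative run, with 31 genes higher in doxycycline against control (23 to 34 over the alternatives, 23 to 32 when 1 array was left out), 35 in recovery against control (34 to 35) and 30 in recovery against doxycycline (27 to 32). Of checks on called named genes 237 of 985 lost the call in doxycycline against control, 205 of 2578 in recovery against control and 181 of 2544 in recovery against doxycycline, and 0 turned. Signal over background limits what can be read, since 42.6% to 45.0% of probes were detected. The alternative with slide or chip as a block was not run, since no chip is named. The cause was not tested for the changes below, except that a minimum difference can only lower a count. Leaving out arrays of the group not compared removes no compared array. It acts through the shared estimate of spread, the choice of probes and the normalization, which were not separated. The median spread was largest for doxycycline (0.217, against 0.117 for control and 0.119 for recovery).

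Doxycycline against control gave 254 genes, and 128 without background correction, 154 without a filter, 129 with the authors' processed values, 3210 with array weights (dominated by doxycycline replicate 3, weight 4.69, against 0.15 for replicate 2), 84 from the compared groups alone, 82 at a difference of at least 1, and 76 to 2614 with 1 array left out: 91, 76 and 82 without control replicates 1, 2 and 3, 2614 and 114 without doxycycline replicates 1 and 3, and 146, 152 and 152 without recovery replicates 1, 2 and 3. Recovery against control gave 2353, and 4361 with array weights, 4037 from the compared groups alone, 473 at a difference of at least 1, and 1351 to 3819 with 1 array left out: 1513 and 1519 without control replicates 2 and 3, 3819 without doxycycline replicate 2, 1351 and 1491 without recovery replicates 2 and 3. Recovery against doxycycline gave 2254, and 4918, 1428 and 366 under the same 3 alternatives, and 1048 to 3279: 1460 without doxycycline replicate 3, 1318, 1048 and 1421 without recovery replicates 1, 2 and 3. Genes differing among the groups numbered 2747, and 6535 with array weights and 1285 to 4923 with 1 array left out: 1804 and 1775 without control replicates 2 and 3, 4923 without doxycycline replicate 1, 1592, 1285 and 1620 without recovery replicates 1, 2 and 3.

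Genes moving back numbered 40, and 63 with offset 50, 9 without background correction, 18 without a filter, 9 with the authors' processed values, 1157 with array weights, 3 at a difference of at least 1, and 3 to 1028 with 1 array left out: 5, 3 and 3 without control replicates 1, 2 and 3, 1028 and 9 without doxycycline replicates 1 and 3, 9, 6 and 13 without recovery replicates 1, 2 and 3. Genes still changed numbered 191, and 117 without background correction, 118 with the authors' processed values, 1377 with array weights, 75 at a difference of at least 1, and 73 to 840 with 1 array left out: 85, 73 and 78 without control replicates 1, 2 and 3, 840 and 103 without doxycycline replicates 1 and 3, and 127 without each recovery replicate. Lists called fell to 1, 1 and 1 with an estimated correlation, and were 9 to 13, 8 to 11 and 6 to 8 with 1 array left out. APC in recovery against doxycycline, -0.01, turned to 0.02 with median scaling and 0.01 with array weights. With 1 array left out it ran from -0.05 to 0.06. Its differences in doxycycline and in recovery against control ran, again with 1 array left out, from 0.01 to 0.33 and from 0 to 0.32. CNMD in doxycycline against control turned to 0.01 with the mean of probes. MUC1 in recovery against doxycycline turned to 0 with array weights and ran from -0.36 to 0.16 (without doxycycline replicate 2). Neither was called.

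With the replicate number as a replicate block the counts were 173, 2041 and 1857, and 15 genes moved back. Each gene's deviation from its group mean was correlated between arrays of the same number. These correlations, from -0.11 to 0.1, give no sign that the numbers pair samples.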

Other observations

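Lists of genes added after the data were seen describe neighbours of the interferon response. Of 17 measured MHC class I antigen presentation genes 7 rose in doxycycline against control (median 0.60, camera adjusted p = 9.5e-09, adjusted p = 0.029 with an estimated correlation), 16 in recovery against control (median 1.39, adjusted p = 3.2e-16, 0.0063 estimated) and 12 in recovery against doxycycline (median 0.89). They included the peptide transporter TAP1 (1.17 in doxycycline, 2.14 in recovery against control) and HLA-E (1.04 and 2.90). Of 13 nucleic acid sensing and interferon genes 3, 9 and 6 rose in the 3 comparisons (camera adjusted p = 1e-04, 1.5e-08 and 1.6e-05). Adjusted p with an estimated correlation was 0.021, 0.0035 and 0.015. DHX58, an RNA-sensor regulator, rose by 1.60 and 3.00, and the RNA receptor TLR3 by 1.14 (0.75 at its other kept probe) and 3.51. IFNB1, interferon beta, was not detected on the control or doxycycline arrays and was at least 5.01-fold higher in recovery than in control.

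Of 13 cell death receptor, caspase and inflammasome genes 1, 8 and 7 rose (camera adjusted p = 0.0016, 5e-08 and 1.1e-05, and 0.073, 0.009 and 0.021 with an estimated correlation), with CASP1 at least 14.7-fold higher in recovery than in control. Of 14 contractile and smooth muscle genes none passed in doxycycline against control, 7 fell in recovery against control and 6 in recovery against doxycycline (camera adjusted p = 0.57, 5.3e-05 and 1.6e-05, and 0.71, 0.032 and 0.025 with an estimated correlation). These lists were chosen after the values were seen, and their p-values do not allow for that choice.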
